A study of Mus musculus with 8 samples.

How the data were processed

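RNA was measured by sequencing in proximal tubular cells of the mouse kidney, the cells that line the first part of the tubule after the glomerulus and take back most of the filtered glucose, salt and amino acids. Per the labels, the mice were of the DBA/2J strain and diabetes was induced with streptozotocin, a drug toxic to the insulin-producing beta cells of the pancreas. The cells were isolated fresh by fluorescence-activated cell sorting and lysed at once, total RNA was purified, and libraries were made with the Ovation RNA-Seq System V2. The 8 libraries formed 4 groups of 2: a control without streptozotocin, named as week 0, and diabetic mice at 2, 4 and 8 weeks. Groups were taken from the source names of the samples and the replicate letters a and b from their titles. The labels do not say whether a and b came from separate animals, so p-values measure the spread between these samples, which may be technical. No non-diabetic libraries of 2, 4 or 8 weeks were among the samples, so diabetes and the passage of time were not separated. Only the diabetic mice had streptozotocin, so an effect of the drug itself was not separated from diabetes either.

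The deposited table held 1 column per library. Its unit was not stated by the labels or the header. The values were taken as FPKM (fragments per kilobase of transcript, scaled to the depth of the library) as deposited by the authors, because they were not whole, had 6 significant digits, and at low levels moved in steps whose size differed between genes. TPM cut from a larger table was not excluded, and the test used would be the same. Per the submitters' processing notes, TopHat and edgeR were used, with no version or role. The genome build, the annotation, the counting tool and the strand setting are not given in the sources used here. Without strand, reads of a noncoding RNA and of a gene that overlaps it on the opposite strand cannot be told apart. The table listed 11923 rows, of which 1, the last, broke off within the line and was left out, leaving 11922. All 11922 IDs had the form used by NONCODE, a database of noncoding RNA genes, and 0 were found in the reference tables of gene names, so the files used here do not pair them with names, positions or transcript classes. The table may hold only part of what was measured, and messenger RNAs were not analysed here.

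Values were transformed to log2(FPKM + 1). Genes at 1 FPKM or more in at least 2 libraries were tested, which left 2319 genes or 19.5% of the table. limma 3.58.1 in R 4.3.3 was fitted to all 8 libraries with 1 mean per group and a variance that followed the mean level, leaving 4 residual degrees of freedom. Contrasts were each diabetic time against control, 4 against 2 weeks and 8 against 4 weeks, and an F test took the 3 contrasts against control together. P-values were adjusted by the Benjamini-Hochberg method over the 2319 genes of each contrast, with 0.05 as the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so single values were tested only within the limma model. Plots were drawn with matplotlib 3.10.9.

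The test was checked on simulated data for 8 weeks against control over 2319 genes. Of 100 genes given a log2 change of 1, 82% were recovered, as were 100% of 100 genes given a change of 2, with 10 false calls. The changed genes were drawn from the more abundant ones only. Recovery among the 1422 least abundant of the 2319 genes was therefore not measured. The simulated noise was independent between libraries and had the same spread in all groups. Deviations shared by same-letter libraries and the tighter 8-week pair, described below, were not simulated, so recovery and false calls in these data may differ. Read totals were not in the table. Where low values moved in whole steps, they gave the depth of each library relative to control a, from 0.941 to 1.19. Of the low values examined, 52.4% were whole multiples of the step within a tolerance of 0.05, against 6.92% to 26.9% after permuting. The value of 1 read had a median of 0.0412 FPKM, with quartiles of 0.0254 and 0.0725, so that 1 FPKM stood for about 24.3 reads at the median step. Total depth stayed unknown, and no counting intervals were computed.

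The design, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The unit turned out to be normalized, and the branch of the design for such a unit was used. The 36 gene lists, the genes to be named in every comparison and the class of noncoding genes by biotype could not be looked up for these IDs and were not tested. The count of noncoding genes changed at any time was therefore that of all genes changed at any time. The rule for named genes took, per comparison with control, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with a mean of 5 FPKM in a group and no overlap between libraries. Since the IDs have no names, only 2 that rose and 2 that fell are printed, from those named at all 3 times, and this narrowing was decided after values were seen. Other genes are described without ID. Among them are the 3 most abundant RNAs of the table, singled out after their values were seen.

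Replicate letters were checked before the groups were compared. The differences between b and a, taken per gene, correlated across 2319 genes between control, 2 and 4 weeks (r from 0.32 to 0.34) and not with those at 8 weeks (r from -0.0034 to 0.025). The labels give no pairing or batch, so the letter was left out of the model, and values within letters are given beside the results. Alternatives were median centring, no filter, limma without the mean-variance trend, pseudocounts of 0.1 and 5, the letter as a block, only the 2 groups compared, an adjusted p of 0.01 for the overlap, and each library left out in turn. Chosen after the data were seen were the letter as a term for control, 2 and 4 weeks alone, and fits without the 8-week group.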

Results

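The 8 libraries profiled noncoding RNAs of sorted proximal tubular cells from control mice and from mice 2, 4 and 8 weeks after streptozotocin, with 2 libraries per group. The study asked which long noncoding RNAs change as diabetic nephropathy, the kidney disease of diabetes, begins. Between 1729 and 2052 genes per library reached 1 FPKM. The group means (n = 2) were 1759 ± 42.4 (SD) in control, 1962 ± 3.54 at 2 weeks, 1883 ± 16.3 at 4 weeks and 2040 ± 17.7 at 8 weeks. Relative depth lay between 0.941 and 1.19, so the libraries were of similar depth, and their total depth is unknown. Libraries of the same group correlated across genes with r from 0.955 to 0.968, and libraries of different groups with r from 0.900 to 0.959. Genes are not independent replicates in these correlations.

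A few RNAs made up much of the table. The 3 most abundant together held 52.7% ± 2.62 (SD, n = 2) of the summed FPKM in control, 51.4% ± 5.20 at 2 weeks, 56.1% ± 4.08 at 4 weeks and 49.7% ± 0.45 at 8 weeks. The most abundant RNA stood at 10293 ± 1463 FPKM in control and at 15964 ± 2029 at 2 weeks, 16457 ± 1860 at 4 weeks and 11378 ± 8.27 at 8 weeks. Its log2 change was 0.63 ± 0.14 (SE) at 2 weeks and 0.68 ± 0.14 at 4 weeks, with limma adjusted p = 0.0431 and 0.0438, and 0.15 ± 0.14 at 8 weeks with adjusted p = 0.493. The second most abundant RNA fell from 7705 ± 609 FPKM in control to 2498 ± 52.1, 4251 ± 315 and 4571 ± 131 at the 3 times, with log2 changes of -1.62, -0.86 and -0.75 (SE 0.10 each) and adjusted p = 0.000683, 0.0162 and 0.00545. The third fell from 3592 ± 724 FPKM to 1255 ± 92.3, 1775 ± 376 and 1950 ± 28.6, with log2 changes of -1.50, -1.02 and -0.87 (SE 0.19 each) and adjusted p = 0.00664, 0.0348 and 0.0219. The rise of the most abundant RNA lay close to the threshold and was lost in 14 of 18 alternative fits at 2 weeks and in 13 of 18 at 4 weeks, where its adjusted p reached 0.221 and 0.205. Its log2 change stayed between 0.49 and 0.78 at 2 weeks and between 0.53 and 0.83 at 4 weeks. With the letter as a block the adjusted p was 0.0110 and 0.0184, and with the letter as a term for control, 2 and 4 weeks 1.35e-05 and 8.76e-06. That term also brought the change of 0.15 at 8 weeks past the threshold (adjusted p = 0.00228), and the step of -0.53 from 4 to 8 weeks went from adjusted p = 0.113 to 2.16e-05, or to 0.0382 with the letter as a block. The fall at 4 weeks was lost in 7 of 18 fits for the second RNA (log2 change from -0.94 to -0.78) and in 11 of 18 for the third (from -1.24 to -0.80), the fall at 8 weeks in 2 and 4 of 16, and the fall of the third at 2 weeks in 1 of 18.

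The first comparison asked which RNAs differed 2 weeks after streptozotocin. Of 2319 genes tested, 100 rose and 64 fell. At least 2-fold changes on the log2(FPKM + 1) scale were seen in 40 of those that rose and 29 of those that fell. NONMMUG023935 was listed at 0 in control a and stood at 0.142 FPKM in control b, and reached 22.4 ± 1.18 FPKM (SD, n = 2) at 2 weeks, a log2 change of 4.45 ± 0.15 (SE) with limma adjusted p = 3.23e-05. NONMMUG009828 rose from 5.64 ± 0.161 to 37.0 ± 8.23 FPKM, a log2 change of 2.5 ± 0.18 with adjusted p = 0.00107. NONMMUG031174 fell from 7.14 ± 0.232 to 0.427 ± 0.216 FPKM, a log2 change of -2.52 ± 0.24 with adjusted p = 0.00267. NONMMUG026094 fell from 24.5 ± 2.69 to 8.80 ± 0.178 FPKM, a log2 change of -1.37 ± 0.14 with adjusted p = 0.00326. With pseudocounts of 5 and 0.1 the change was 2.44 and 7.18 for NONMMUG023935 and -1.16 and -3.84 for NONMMUG031174. The 8 RNAs named for their rise rose by 1.69 to 4.45 on the log2 scale, and the 8 named for their fall by 1.37 to 2.52. Named RNAs had a mean of at least 5 FPKM in a group and no overlap between libraries. Other called genes may have changed more.

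For 2 weeks against control, the log2 changes of all genes within letter a correlated with those within letter b with r = 0.61, and with r = 0.36 when the letters were crossed. An unadjusted p under 0.05 was reached by 577 genes. In 54.2% of genes the libraries of the groups did not overlap, where values unrelated between all libraries would give 33.3%. Same-letter libraries deviated together, so 33.3% is no exact baseline here. With median centring 73 rose and 80 fell, and with the letter as a term for control, 2 and 4 weeks 343 changed, among them all 164. The count fell to 41 with only these 2 groups in the fit and to 93 without the 8-week group, and it was 66 without control a, 35 without control b, 28 without 2 weeks a, 52 without 2 weeks b, 91 without 8 weeks a and 92 without 8 weeks b.

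**Figure D1:**
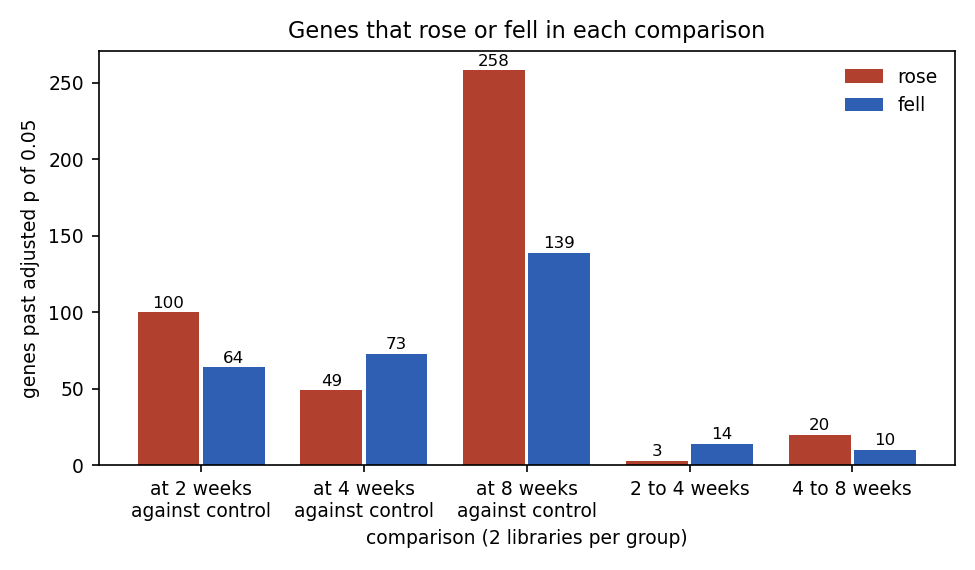
Numbers of genes (y axis) that rose (red bars) or fell (blue bars) past a limma adjusted p of 0.05 in each of 5 comparisons (x axis), with 2 libraries per group. At 8 weeks 258 genes rose and 139 fell, more than at 2 weeks (100 and 64) or 4 weeks (49 and 73), and with median centring the larger number at 2 and 8 weeks was of genes that fell (80 and 190).

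At 4 weeks 49 genes rose and 73 fell against control. At least 2-fold changes were seen in 15 that rose and 26 that fell. NONMMUG023935 reached 28.5 ± 4.36 FPKM (SD, n = 2), a log2 change of 4.78 ± 0.15 (SE) with limma adjusted p = 1.98e-05, and NONMMUG009828 reached 44.9 ± 5.88 FPKM, a change of 2.78 ± 0.18 with adjusted p = 0.00154. NONMMUG031174 stood at 0.605 FPKM in 4 weeks a and was listed at 0 in 4 weeks b, a change of -2.68 ± 0.24 with adjusted p = 0.00496. NONMMUG026094 was at 7.37 ± 0.0575 FPKM, a change of -1.60 ± 0.14 with adjusted p = 0.00496. Both falls missed the threshold with only these 2 groups in the fit (adjusted p = 0.0670 each), and that of NONMMUG026094 also without control a (adjusted p = 0.0625). Over the alternatives the adjusted p lay between 0.000826 and 0.0670 for NONMMUG031174 and between 0.00126 and 0.0670 for NONMMUG026094. NONMMUG031174 was below the filter, and so not tested, in the fits without control a and without control b. With pseudocounts of 5 and 0.1 the change was 2.72 and 7.51 for NONMMUG023935 and -1.20 and -4.77 for NONMMUG031174. The 8 RNAs named for their rise rose by 0.95 to 4.78 on the log2 scale, and the 8 named for their fall by 1.12 to 2.68. Called genes that stayed under a mean of 5 FPKM in both groups, or whose libraries overlapped, were not named. Some of the larger rises are among them.

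For 4 weeks, the log2 changes of all genes correlated between the letters with r = 0.55, and with r = 0.27 when the letters were crossed. An unadjusted p under 0.05 was reached by 548 genes, and 52.4% of genes had no overlap between libraries. All groups share a single error in the main fit, and the 8-week pair lowers it for abundant genes. Over the 43 most abundant genes, the SD of b minus a on the log2 scale was 0.12 at 8 weeks and 0.43 at 4 weeks. Over the 1422 least abundant it was 0.39 and 0.42. The 122 calls at 4 weeks and the 164 at 2 weeks rest in part on that shared error. The count at 4 weeks depended on the libraries fitted. It was 2 with only these 2 groups and 8 without the 8-week group. It was 298 with the letter as a term for control, 2 and 4 weeks, and 237 without the 8-week group and with the letter as a block. It was 3 without control a, 4 without control b, 41 without 2 weeks a, 42 without 2 weeks b, 6 without 4 weeks a, 21 without 4 weeks b and 8 without 8 weeks a and 8 without 8 weeks b.

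At 8 weeks 258 genes rose and 139 fell against control. At least 2-fold changes were seen in 85 that rose and 50 that fell. NONMMUG023935 reached 51.9 ± 2.23 FPKM (SD, n = 2), a log2 change of 5.63 ± 0.15 (SE) with limma adjusted p = 6.34e-06, and NONMMUG009828 reached 60.1 ± 5.37 FPKM, a change of 3.20 ± 0.18 with adjusted p = 0.000237. NONMMUG026094 fell to 0.207 ± 0.129 FPKM, a change of -4.40 ± 0.14 with adjusted p = 9.87e-06. NONMMUG031174 was at 0.393 ± 0.147 FPKM, a change of -2.55 ± 0.24 with adjusted p = 0.00221. Another RNA, among the largest rises and described without its ID, went from 0.630 FPKM in control to 66.6 FPKM. With pseudocounts of 5 and 0.1 the change was 3.49 and 8.38 for NONMMUG023935, -1.17 and -3.91 for NONMMUG031174, and -2.50 and -6.38 for NONMMUG026094. The 8 RNAs named for their rise by the same rule rose by 1.94 to 5.63 on the log2 scale. The 8 named for their fall fell by 1.61 to 4.40.

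For 8 weeks, whose letters did not go with those of control, the log2 changes of all genes correlated between letters with r = 0.66, and with r = 0.65 when the letters were crossed. An unadjusted p under 0.05 was reached by 773 genes, and 63.2% of genes had no overlap between libraries. With median centring 164 rose and 190 fell, and with the letter as a term for control, 2 and 4 weeks 636 changed. The count was 360 with only these 2 groups in the fit, 171 without control a, 153 without control b, 60 without 8 weeks a and 82 without 8 weeks b.

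**Figure D2:**
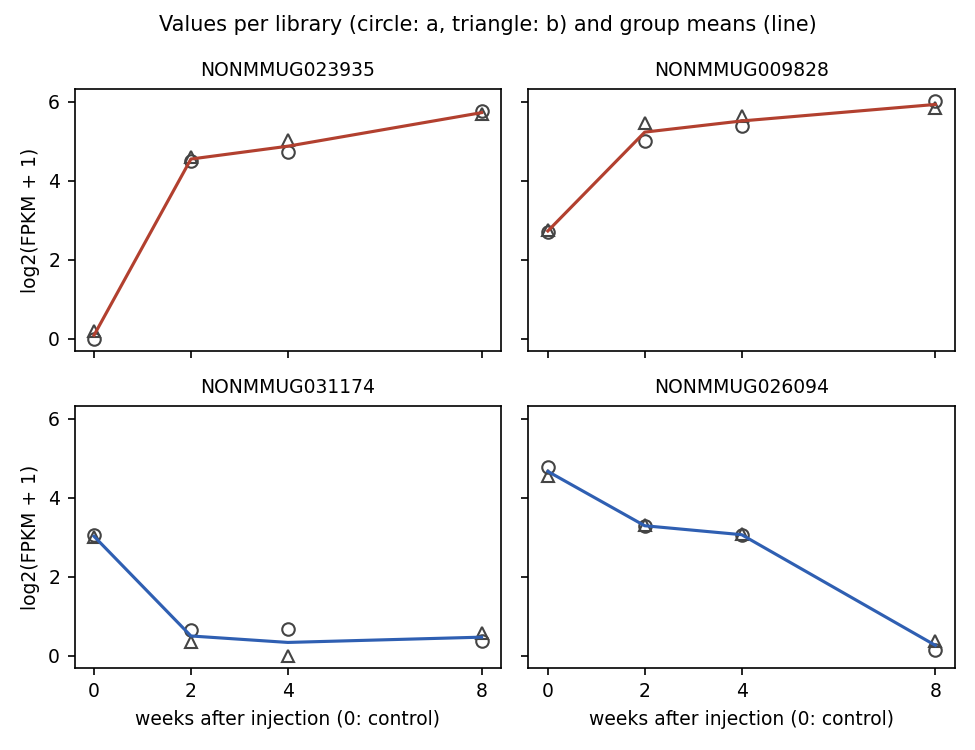
Level of 4 RNAs as log2(FPKM + 1) (y axes) against weeks after streptozotocin (x axes, 0 for control), with a circle for library a, a triangle for library b and a line through the group means of 2 libraries. NONMMUG023935 and NONMMUG009828 lay above both control libraries at each time, and NONMMUG031174 and NONMMUG026094 below, the last reaching 0.207 FPKM at 8 weeks. The rule that chose these 4 RNAs required such a lack of overlap with control.

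The F test over the 3 times asked which RNAs changed at any time. It found 266 genes, and 688 at an unadjusted p under 0.05. Of the 266, 142 lay above control at all 3 times and 90 below, while 34 lay on both sides. The departure from control was largest at 8 weeks in 105 of the 142 and in 44 of the 90. The count was 161 with no filter, where 7531 genes were tested, and 543 with the letter as a term for control, 2 and 4 weeks. Leaving out 1 library gave 39 without control a, 26 without control b, 100 without 2 weeks a, 110 without 2 weeks b, 123 without 4 weeks a, 138 without 4 weeks b, 36 without 8 weeks a and 42 without 8 weeks b.

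Many of the RNAs changed at several times. At all 3 times 36 genes rose and 31 fell, 67 in all. The split was 29 and 37 with median centring, 21 and 42 with no filter, and 38 and 16 with a pseudocount of 0.1. Independent lists would share 0.356 genes, a value that leaves out the shared controls. In 100 simulations, unchanged groups set against a shared pair of simulated controls had 0 in common, as such groups have hardly any calls to share. All libraries were redrawn, so a deviation common to the 2 real controls was not part of the simulations. Of the 397 genes changed at 8 weeks, 122 had changed the same way at 2 weeks and 93 at 4 weeks. At both 2 and 4 weeks 39 rose and 40 fell, where independent lists would share 2.11 and 2.01, and 0 genes changed in opposite directions in any pair of times. The log2 changes correlated across genes with r = 0.75 between 2 and 4 weeks, 0.76 between 2 and 8 weeks and 0.69 between 4 and 8 weeks, where simulated unchanged groups gave 0.50 for each. The covariances were 0.157, 0.207 and 0.174, against simulated values of 0.0302, 0.0300 and 0.0302. Between changes taken from single libraries with no library in common, r lay between 0.45 and 0.58, where 100 simulations of unchanged groups gave -0.10 to 0.09. The 2 control libraries cannot be split and still give 2 per comparison, so part of the excess may come from them. The 67 genes became 157 with the letter as a term for control, 2 and 4 weeks and 6 at an adjusted p of 0.01. Without 1 library the count was 3 (control a), 4 (control b), 13 (2 weeks a), 18 (2 weeks b), 6 (4 weeks a), 15 (4 weeks b), 7 (8 weeks a) and 7 (8 weeks b).

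Steps between successive times were tested directly. From 2 to 4 weeks 3 genes rose and 14 fell. Of the 14, 12 had risen at 2 weeks and 1 was past the threshold against control at 4 weeks. The median log2 change from control of the 14 was 1.74 at 2 weeks, 0 at 4 weeks and 1.00 at 8 weeks. The 2-week libraries enter both the step and the comparison with control at 2 weeks, which favours such a course in genes chosen for the step. The 3 that rose had all fallen at 2 weeks, among them the second most abundant RNA of the table (log2 change 0.76 ± 0.10, SE, limma adjusted p = 0.0241). None of the 4 RNAs printed with their IDs differed between 2 and 4 weeks (adjusted p from 0.568 to 0.889). At an unadjusted p under 0.05 there were 225 genes. The libraries did not overlap in 38.6% of genes, where values unrelated between all libraries would give 33.3%. Same-letter libraries of 2 and 4 weeks deviated together, so the 2 shares cannot be compared closely. The count was 2 with only these 2 groups in the fit, 8 without the 8-week group and 28 with the letter as a term for control, 2 and 4 weeks. Without 1 library it was 10 (control a), 11 (control b), 2 (2 weeks a), 3 (2 weeks b), 2 (4 weeks a), 1 (4 weeks b), 8 (8 weeks a) and 8 (8 weeks b). The step of the second most abundant RNA was lost in 12 of 18 alternative fits, with adjusted p up to 0.284 and a log2 change that stayed between 0.69 and 0.84.

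From 4 to 8 weeks 20 genes rose and 10 fell. Of the 20, 19 were also above control at 8 weeks by the test, and 9 of the 10 were below it, calls that share the 8-week libraries with the step. NONMMUG026094 fell from 7.37 to 0.207 FPKM (log2 change -2.80 ± 0.14, SE, n = 2 each, limma adjusted p = 0.000228), a change of -1.25 with a pseudocount of 5 and of -4.67 with one of 0.1. NONMMUG023935 went from 28.5 to 51.9 FPKM, a log2 change of 0.85 ± 0.15 that missed the threshold (adjusted p = 0.0535) and passed it with a pseudocount of 5, with the letter as a block and with the letter as a term for control, 2 and 4 weeks (adjusted p = 0.0290, 0.0375 and 0.00793; 0.00793 to 0.304 over all alternatives). At an unadjusted p under 0.05 there were 421 genes, and 50.3% had no overlap between libraries. With median centring 11 rose and 15 fell. The count was 72 with the letter as a block, 205 with the letter as a term for control, 2 and 4 weeks, 62 with a pseudocount of 5 and 13 with only these 2 groups. Without 1 library it was 18 (control a), 19 (control b), 17 (2 weeks a), 18 (2 weeks b), 7 (4 weeks a), 6 (4 weeks b), 7 (8 weeks a) and 8 (8 weeks b).

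**Figure D3:**
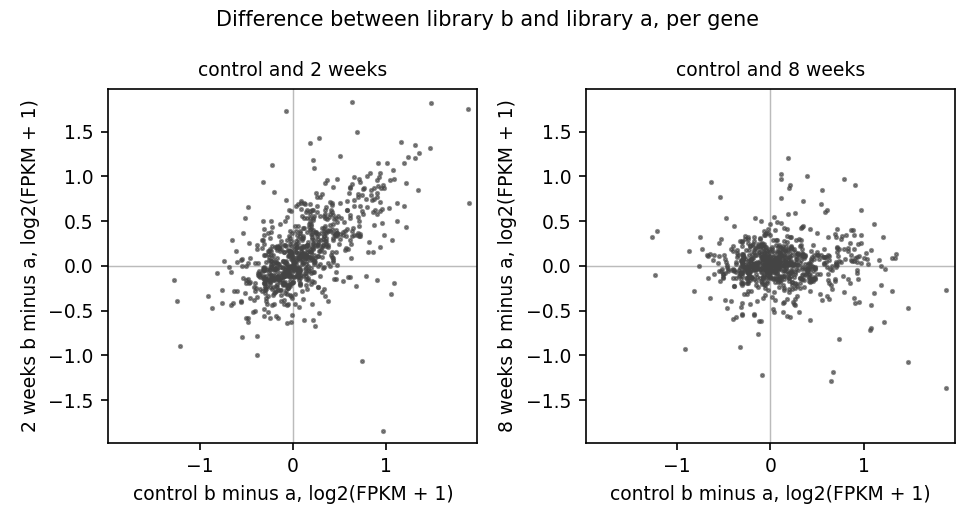
Difference between library b and library a on the log2(FPKM + 1) scale for 746 genes at 5 FPKM or more in at least 2 libraries, with control on the x axes and 2 weeks (left) or 8 weeks (right) on the y axes. Each point is a gene. The differences of control went with those of 2 weeks (r = 0.61) and not with those of 8 weeks (r = -0.03).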

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

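The tests of depth, letters, control libraries, separate preparation and fixed total were chosen after the results they bear on were seen. The bound for a low background at 8 weeks was set beforehand.

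The level differed between diabetic times, by the direct test, in 17 genes between 2 and 4 weeks and in 30 between 4 and 8 weeks. Among them, the second most abundant RNA stood 0.76 higher on the log2 scale at 4 than at 2 weeks (adjusted p = 0.0241), and NONMMUG026094 changed by -2.80 from 4 to 8 weeks (adjusted p = 0.000228).

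More genes changed at 8 weeks (397) than at 2 or 4 weeks (164 and 122). The order against 2 weeks turned without 8 weeks a and without 8 weeks b. Such a fit leaves a single library at 8 weeks while the 2-week group keeps both, so it cannot weigh that order. With the letter as a term for control, 2 and 4 weeks, the counts at 8 and 2 weeks went from 397 and 164 to 636 and 343, a ratio of 1.85. Spread between the letters therefore does not account for the whole of the larger number at 8 weeks. Nor does a single control library, since the ratio was at least 2.59 without either. A low background over all loci at 8 weeks would lift low genes. The 2947 genes at 0.1 to 1 FPKM in control gained a median of 0.0818 FPKM (0.0685 to 0.0937, 95% bootstrap interval over genes). That was under the bound of 0.1 but more than at 2 weeks (0.0430) and 4 weeks (0.0327), so a smaller background stays possible. A background of that size does not account for the 139 genes that fell, against 64 and 73 at 2 and 4 weeks. The 258 risen genes gained a median of 1.85 FPKM, but they were chosen for their rise, so their gain is no test of a background. Separate preparation of the 8-week libraries remains open, as the labels give no batch: of the 249 genes called at 8 weeks alone, 16 differed between 8 and 4 weeks, and a longer time with diabetes cannot be told apart from such a batch.

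Libraries of the same letter deviated together in control, at 2 and at 4 weeks, with r of at least 0.315 across genes, and not at 8 weeks. Depth alone does not account for it, because library b was deeper than library a by 1.15 times at 8 weeks, at least as much as in the other groups (1.09 to 1.12). Shared handling of same-letter libraries up to 4 weeks may be the source, and it stays open because the labels name no batch. No biological explanation was tested.

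In the main fit the most abundant RNA rose at 2 and 4 weeks while the second and the third fell. The rise was lost in 14 of 18 alternative fits at 2 weeks and in 13 of 18 at 4 weeks. The checks below bear only on the fall of the second at 2 weeks. Under a fixed total of this table, the larger share of the most abundant RNA at 2 weeks would change all other genes alike, by about -0.358 on the log2 scale. The other 2316 genes had a median log2 change of 0.073 at 2 weeks (interquartile range 0.53). The second most abundant RNA changed by -1.62, a larger fall than a fixed total would give. Differences between letters do not account for its fall either, which was -1.52 within letter a and -1.72 within letter b. RNA from other cells in the sort was not tested, and an effect of diabetes remains a hypothesis.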

How the results depend on the processing

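The fits with the letter as a term for control, 2 and 4 weeks and those without the 8-week group were chosen after the data were seen. With the former, more genes passed: 343, 298 and 636 at 2, 4 and 8 weeks, 28 from 2 to 4 weeks, 205 from 4 to 8 weeks, 543 at any time and 157 at all 3 times. The replicate letter as a block in all groups moved only the step from 4 to 8 weeks by over 1.5 times (72 genes), with 197, 172 and 479 genes at the 3 times, 16 from 2 to 4 weeks, 330 at any time and 88 at all 3 times. Without the 8-week group 93 and 8 genes passed at 2 and 4 weeks and 8 between them, and with the letter as a block as well 238, 237 and 21. With only the 2 groups compared, leaving 2 residual degrees of freedom, 41 and 2 genes passed at 2 and 4 weeks, 2 from 2 to 4 weeks and 13 from 4 to 8 weeks. No filter gave 161 genes at any time among 7531 tested, a pseudocount of 5 gave 62 from 4 to 8 weeks, and an adjusted p of 0.01 left 6 genes at all 3 times. Of the main calls, 110 of 164 at 2 weeks, 46 of 122 at 4 weeks and 266 of 397 at 8 weeks passed again with no filter. The same held for 12 of 17 from 2 to 4 weeks and 14 of 30 from 4 to 8 weeks. Where no reason is given, the cause was not tested.

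Leaving out each library in turn left 3 residual degrees of freedom, and the lone library of a group was assumed to vary like the other groups. The counts ranged from 28 to 122 at 2 weeks, 3 to 42 at 4 weeks, 60 to 372 at 8 weeks, 1 to 11 from 2 to 4 weeks, 6 to 19 from 4 to 8 weeks, 26 to 138 at any time (the count of noncoding genes as well) and 3 to 18 at all 3 times. Of 590 fits of the 4 printed and 3 most abundant RNAs over comparisons and alternatives, 516 kept their side of the threshold, 67 lost a call, 7 gained one and 0 turned a called direction. The 4 printed RNAs account for 332 of these fits, with 3 calls lost and 3 gained. NONMMUG031174 was below the filter in the fits without control a and without control b. Its calls there are left out and not counted as lost, so its dependence on a single control library was not measured. Comparisons without a call in the main fit are among the 590 and had none to lose, so the 516 overstate how well calls held. Most lost calls were of the 3 most abundant RNAs, as in 14 of 18 fits for the first at 2 weeks. Median centring, limma without trend and a pseudocount of 0.1 kept each total of changed genes within 1.5 times, though not each count of risen or fallen genes. Fits of the 36 gene lists were not run, because the IDs could not be matched to names, and size factors and count tests were not run, because the values are not counts. Depth limits the low genes: 1 FPKM stood for about 24.3 reads at the median step.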

Other observations

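The counts of turning genes and of group pairs were chosen after the values were seen. The test of regrouped libraries was added after the counts of changed genes were seen, with its bound set before the splits were counted.

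Some RNAs stood apart at 4 weeks from the times before and after. Of the 6 genes that changed at both steps, 5 fell from 2 to 4 weeks and rose again from 4 to 8 weeks, and 1 did the opposite. Both steps share the 4-week libraries, which favours opposite signs, and the 17 genes of the first step became 1 to 11 when a library was left out. The clearest went from 0.630 FPKM in control to 14.5 at 2 weeks, 0.787 at 4 weeks and 66.6 at 8 weeks (means of 2 libraries), and is described without its ID. Over the 2319 genes tested, the 4 libraries of 2 and 8 weeks lay all above or all below the 4 libraries of control and 4 weeks in 226 genes (9.75%), above in 175 and below in 51. The same held in 154 genes (6.64%) for 4 and 8 weeks against control and 2 weeks. It held in 129 genes (5.56%) for 2 and 4 weeks against control and 8 weeks. Values unrelated between all libraries would give 2.86%. Libraries of a group resemble each other, so any difference between groups lifts each of these shares above that value. Only the shares can be set against each other. With median centring the counts were 190 (96 above and 94 below), 148 and 136. Centring removes the median log2 change from control over all genes, which was 0.072 at 2 weeks, 0.0060 at 4 weeks and 0.079 at 8 weeks. The excess of genes above at 2 and 8 weeks went with that shift. Centring cannot tell whether the shift came from scaling or from the RNAs. No explanation was tested for the turn.

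The grouping of the libraries was set against other splits into 4 groups of 2. Of 100 splits, the real one included, 1, the real one, gave 266 genes or more in the F test, and the highest other gave 230. That other split kept control and 8 weeks together and exchanged partners between 2 and 4 weeks so that same-letter libraries were joined. Genes that set control or 8 weeks apart count in both splits, so the 2 numbers do not compare letter with time. The real grouping gave more genes than any other split counted, so libraries of a group resembled each other. The splits cannot tell time with diabetes from a difference between animals or preparations, as a and b may share them. With the letter as a block 330 genes changed at any time.

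Library pairs were tighter at 8 weeks among abundant RNAs. The SD of the difference between b and a over the 43 most abundant genes was 0.12 on the log2 scale at 8 weeks, against 0.41 in control, 0.44 at 2 weeks and 0.43 at 4 weeks, while over the 1422 least abundant genes it was 0.39 in each of control, 2 and 8 weeks and 0.42 at 4 weeks.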
